A study of Mus musculus with 15 samples.

How the data were processed

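Gene expression was measured on single-colour Affymetrix Mouse Gene 1.0 ST arrays in Myc-CaP cells, a cell line derived from a prostate tumour of a mouse that carries a Myc transgene. The 15 arrays fall into 5 groups of 3: cells with an empty vector (VEC), and cells with wild-type Twist1 (WT), with the F191G form mutated in the Twist box, or with the AQA or DQD form. The labels name the replicates A, B and C, and they do not say whether these came from separate cultures. The p-values therefore measure the spread between these arrays, which may be partly technical.

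The deposited table holds log2 values of 23811 probe sets, and per the submitters' processing notes these were made with RMA (background correction, quantile normalization and summarization of probes into probe sets) and examined with limma. Versions of both tools are not given in the sources used here. The series' design text adds a normalization by Twist1 expression, and its form is not given. Whether it changed the deposited values stays unknown, as does the rule by which probe sets were kept. The deposited log2 values run from 1.41 to 13.6, with array medians between 6.31 and 6.42. No detection calls were used here, and the number of arrays limits the precision.

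Of the probe sets, 20852 carry 1 gene symbol in the platform annotation, 1440 carry several and 1519 are not listed there. Symbols were checked through the gene identifier, which matched for 20805 probe sets, and 0 symbols were updated. Probe sets with several symbols named no gene. For each symbol the probe set with the highest mean over the 15 arrays was kept, a choice that applied to 846 genes, which left 19297 genes. No filter on dim genes was applied.

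The labels give 2 array batches, with 8 arrays in batch A and 7 in batch B. Batch A holds 2 of the 3 arrays of VEC, WT and AQA, and 1 of the 3 of DQD and F191G. Linear models with group and batch as fixed terms were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (9 residual degrees of freedom, 3.93 prior degrees of freedom). Adjusted p-values follow Benjamini and Hochberg over the 19297 genes, and genes under 0.05 are called changed. Fold changes are log2 differences with their standard error (SE), and levels are means ± SD of 3 arrays on the deposited log2 scale.

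A total of 23 gene lists was written from textbook knowledge. Each was tested with camera at its preset inter-gene correlation of 0.01, again with the correlation estimated from these arrays, and with fry. List p-values were adjusted over the 23 lists within each comparison. Camera compares the moderated t-statistics of a list with those of all other genes. A common log2 shift moves these more for genes with a small SE, so it can still move a list. Camera was not run with median centring. None of the list calls in any of the 8 comparisons held with an estimated correlation, which reached 0.879 for the cell cycle list and 0.53 for the interferon list. Beside a list's count over all genes in the full model, a count adjusted over the list alone is given.

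Genes named in the text follow a rule. For WT against VEC, F191G against VEC and F191G against WT these are the 10 called genes with the largest rise and the 10 with the largest fall, for the other comparisons the 4 and 4, plus up to 4 members of each described list with the smallest p, Twist1, and a set of epithelial-mesenchymal transition genes. Genes known only by predicted or clone names were passed over. The groups, comparisons, lists, rule and alternatives were fixed before the data were examined. Names outside the rule are marked as chosen after their values were seen.

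The alternatives were a model without batch, the replicate letter as a block with and without batch, the Twist1 value as a covariate, only the arrays of the groups compared, quantile normalization again, median centring, leaving out the dimmest 33.3% of genes, all probe sets, a variance trend with robust moderation, array weights, each batch alone, and leaving out each array in turn. Leaving WT replicate A out of comparisons it is not part of, and leaving Ddr2, a collagen receptor gene that the stress response list holds, out of that list were added after the data were seen. Agreement between comparisons that share arrays was set beside 100 simulations of unchanged groups. The model was tested on simulated data with 200 changed genes per comparison: for WT against VEC it recovered 98% of genes changed by 1 and 79% of genes changed by 0.5 on the log2 scale, with 7 unchanged genes among 184 calls. Simulated genes vary independently, which real genes do not. Figures were drawn with matplotlib 3.10.9.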

Results

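The data comprise 15 expression arrays of Myc-CaP mouse prostate cancer cells, 3 for each of an empty vector (VEC), wild-type Twist1 (WT) and the Twist1 forms F191G, AQA and DQD. Twist1 is a basic helix-loop-helix transcription factor known for its part in epithelial-mesenchymal transition. Values are deposited log2 values, n = 3 arrays per group throughout, with 19297 genes tested. Pairwise correlations between arrays ran from 0.975 to 0.998. The lowest involved WT replicate A, without which the lowest was 0.992.

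The Twist1 probe set read 6.43 ± 0.29 in VEC, 6.79 ± 0.06 in WT, 6.68 ± 0.24 in AQA, 6.78 ± 0.18 in DQD and 6.75 ± 0.10 in F191G. The WT difference from VEC was 0.36 (SE 0.147, limma adjusted p = 0.129), and Twist1 passed the test in none of the 4 forms against VEC. Over the 12 arrays with any Twist1 form and the 3 VEC arrays, the difference was 0.32 (exact two-sided permutation p = 0.022), and 9 of the 12 lay above the highest VEC array. Within batch A the difference was 0.11 (6 against 2 arrays) and within batch B 0.68 (6 against 1), with an exact permutation p of 0.036 when arrays were exchanged only within batches. Neither permutation test was among the tests planned for Twist1. Both exchange single arrays, as though arrays of the same form were independent, which the labels do not show. Without VEC replicate C, whose value was 6.13, the WT difference was 0.17. What part of the transcript the probe set covers is not given in the sources used here, so these values do not check the labels.

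The first comparison named by the design, WT against VEC, asks which genes wild-type Twist1 changes. Interferon-stimulated genes were among the largest rises: Ifit3 went from 4.27 ± 0.70 to 9.29 ± 0.56, a rise of 5.02 (SE 0.525, adjusted p = 0.00091). Ifit3b rose by 3.23 (SE 0.482) and Ifitm3 by 2.33 (SE 0.541). Angptl7, an angiopoietin-like factor, rose by 4.42 (SE 0.837), the small proteoglycan gene Ogn by 4.24 (SE 0.912), and Lgals3bp, whose product binds galectin, by 3.16 (SE 0.429). Further rises were those of the apolipoprotein gene Apof up 2.53 (SE 0.438), the fibrinogen chain gene Fgb up 2.50 (SE 0.697) and Igfbp5, an insulin-like growth factor binding protein, up 2.46 (SE 0.596). Pdcd4, an inhibitor of translation initiation, rose by 2.38 (SE 0.233, adjusted p = 0.000753). The keratin genes Krt19, Krt15 and Krt6a fell by 2.13 (SE 0.523), 1.73 (SE 0.258) and 1.36 (SE 0.313). The neutrophil chemokine gene Cxcl5 fell by 1.30 (SE 0.124, adjusted p = 0.000753) and the peptide hormone gene Cck by 1.67 (SE 0.468), and the chemokine gene Ppbp changed by -1.51 (SE 0.362). The others among the 10 largest falls were Trip13, down by 1.40 (log2 fold change -1.399), the condensin gene Ncapg2 by 1.40 (-1.395), the primase subunit gene Prim1 (-1.33, SE 0.367) and Wdr76 (-1.29, SE 0.353). Some of these sizes rested on single arrays. Krt19 read 8.62 ± 1.57 in VEC and 6.49 ± 0.04 in WT, and without VEC replicate A, at 10.28, the change was -1.25, without VEC replicate B -2.90. WT arrays were spread for Angptl7 (9.62 ± 2.01), Ogn (8.77 ± 2.18), Fgb (7.81 ± 1.74) and Igfbp5 (10.69 ± 1.38). Without WT replicate A these 4 changes were 3.59, 3.26, 1.52 and 1.76, the last pair no longer called (adjusted p = 0.105 and 0.0699), and without WT replicate B they were 5.62, 5.495, 3.33 and 3.20. Without WT replicate A, Ppbp changed by -0.97 and Ncapg2 by -0.84, and Cck (-0.93), Trip13 (-0.82), Prim1 (-0.74) and Wdr76 (-0.72) lost their calls. Of these 20 genes, 12 were still called without WT replicate A, 12 without VEC replicate A, 15 without VEC replicate B and 6 without VEC replicate C.

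In all, 2466 genes were called between WT and VEC, 1362 higher and 1104 lower, of which 134 rose and 57 fell at least 2-fold. The count rested on single arrays: it was 844 without WT replicate A (822 shared with the full set), 128 without VEC replicate C and 1314 without VEC replicate A. Median centring gave 1106 higher and 1165 lower, which turns the majority. The count was 0 within batch A by limma (2903 genes at an unadjusted p under 0.05) and 293 within batch B, where each group has 1 array and the spread comes from other groups. The count fell to 10 with only the 6 arrays compared. With the Twist1 value as a covariate it was 17 by limma (3776 at an unadjusted p under 0.05). Twist1 is the introduced gene and read higher in WT than in VEC, so this covariate overlaps with the comparison itself. The lower count therefore does not show that the changes follow the Twist1 level. The same limit holds for the other forms against VEC.

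Of the 41 measured interferon response genes, 28 rose and 0 fell in WT against VEC (33 and 0 adjusted over the list alone), with a median change of 0.996 and camera adjusted p = 1.66e-16. The call was lost with an estimated correlation, at adjusted p = 0.377. Examples are the RNA sensor gene Ddx58 (1.996, SE 0.371) and the interferon signalling factors Irf9 (1.13, SE 0.214) and Stat2 (0.997, SE 0.191). The count of members that rose was 1 without VEC replicate C, 11 without VEC replicate B, 18 without WT replicate B and 17 without WT replicate C. The list mean of the 3 WT arrays lay 0.95 to 1.26 above the VEC mean, and the VEC arrays themselves ranged from -0.28 to 0.40.

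Of 53 measured cell cycle genes, 15 fell and 0 rose (48 fell adjusted over the list alone), with camera adjusted p = 2.17e-16, and adjusted p = 0.457 with an estimated correlation. Fry, which tests a list without comparing it with other genes, did not call it (adjusted p = 0.0709). The replication genes Cdc45, Cdt1, Mcm4 and Tyms changed by -1.02 (SE 0.224), -1.002 (SE 0.230), -1.13 (SE 0.263) and -0.996 (SE 0.237), and without WT replicate A by -0.66, -0.65, -0.71 and -0.63. The list mean was -1.49 on WT replicate A and -0.38 and -0.39 on replicates B and C. The count of members that fell was 7 without WT replicate A, 8 without VEC replicate B, 42 without WT replicate B and 38 without WT replicate C. By limma it was 0 without VEC replicate A or VEC replicate C (30 and 35 members at an unadjusted p under 0.05). Of 43 Myc targets and ribosome biogenesis genes, 21 fell and 0 rose (28 fell and 1 rose adjusted over the list alone), among them the iron uptake receptor gene Tfrc (-0.70, SE 0.126) and the nucleolar genes Fbl (-0.62, SE 0.117), Gnl3 (-0.42, SE 0.086) and Nolc1 (-0.46, SE 0.096). Its camera adjusted p was 1.45e-12, and adjusted p = 0.377 with an estimated correlation. The count was 7 without WT replicate A, 5 without VEC replicate A, 11 without VEC replicate B and 0 by limma without VEC replicate C (28 at an unadjusted p under 0.05).

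Of 36 genes of cholesterol and lipid synthesis, 17 fell and 1 rose in WT (22 and 4 adjusted over the list alone), with camera adjusted p = 2.73e-08, and adjusted p = 0.377 with an estimated correlation. The sterol enzymes Dhcr7, Sqle and Msmo1 fell by 0.64 (SE 0.072), 0.88 (SE 0.123) and 0.93 (SE 0.145), and the fatty acid elongase gene Elovl5 fell by 0.49 (SE 0.084). The count that fell was 10 without WT replicate A, 11 without VEC replicate B and 3 without VEC replicate C. Of 44 genes of the unfolded protein and integrated stress response, 16 rose and 1 fell (18 and 4 adjusted over the list alone), including the chaperone gene Hspa5 (0.40, SE 0.070), the transcription factor gene Xbp1 (0.85, SE 0.156), Cth (0.58, SE 0.105) and Ddr2 (0.56, SE 0.079), with camera adjusted p = 9.75e-05, and adjusted p = 0.377 with an estimated correlation. Ddr2 encodes a collagen receptor kinase and also stands in 2 other lists; without it 15 rose and 1 fell, with camera adjusted p = 0.000319. The count that rose was 10 without WT replicate A and 1 without VEC replicate C. Of 32 p53 targets and cell cycle inhibitors, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with Trp53inp1 up 2.18 (SE 0.301), the antiproliferative gene Btg2 up 2.22 (SE 0.427), Mdm2 up 0.61 (SE 0.096) and Ccng1 down (-0.23, SE 0.064). Its camera adjusted p was 0.0433, and adjusted p = 0.377 with an estimated correlation. Leaving out VEC replicate B, VEC replicate C or WT replicate C ended this call (adjusted p = 0.075, 0.141 and 0.165), as did leaving out the dimmest genes (0.156), and 3 members rose without WT replicate A or C and 2 without VEC replicate C.

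None of the other 17 lists was called by camera in WT against VEC, with adjusted p from 0.0572 for TGF-beta and BMP signalling to 0.976. Counts adjusted over the list alone follow in brackets. Among 44 mesenchymal factors 4 rose and 3 fell (4 and 4), among 49 epithelial junction and keratin genes 2 and 4 (3 and 5), and among 51 collagens and matrix proteins 1 and 2 (0 and 2). Of 41 matrix proteases and inhibitors 6 rose and 1 fell (6 and 1), of 38 integrin and focal adhesion genes 1 and 2 (0 and 0), of 42 Hox genes 1 and 2 (0 and 0), and of 39 basic helix-loop-helix factors 6 and 0 (6 and 0). For TGF-beta and BMP signalling 6 of 49 rose (9), and for growth factors and receptor kinases 11 of 57 rose and 0 fell (11 and 1). Wnt and Notch signalling had 4 rising and 1 falling of 54 (4 and 1), and cytokines 2 and 2 of 49 (2 and 2). Hypoxia and glycolysis had 6 rising of 48 (6), androgen response 6 rising and 2 falling of 39 (6 and 2), and oxidative stress 4 and 2 of 41 (4 and 6). Markers of other cell types were 1 rising and 1 falling of 25 neural genes (1 and 1), 1 rising of 26 haematopoietic genes (0), the macrophage gene Cd68, and 0 of 32 endothelial and fibroblast genes by limma (0, with 2 at an unadjusted p under 0.05). The haematopoietic list mean was 0.165 above VEC on WT replicate A, the highest of the 15 arrays, and -0.026 and 0.012 on WT replicates B and C. Summed over the 17 lists, 62 members rose and 22 fell, against 20 and 8 without WT replicate A, 6 and 2 without VEC replicate C, 41 and 12 without VEC replicate A and 38 and 24 without VEC replicate B. Growth factors and receptor kinases then had 2 rising without WT replicate A, 1 without VEC replicate C and 4 without VEC replicate A. Without WT replicate A 3 proteases or inhibitors, 2 basic helix-loop-helix, 2 TGF-beta or BMP and 2 hypoxia genes rose, 3 androgen response genes rose and 1 fell, 2 oxidative stress genes fell, and 2 mesenchymal factors rose with 0 falling by limma (10 of either direction at an unadjusted p under 0.05). In each of the other lists at most 2 rose and 2 fell without that array.

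The classical markers of epithelial-mesenchymal transition showed no called change between WT and VEC. Cdh1, which encodes E-cadherin, read 5.72 ± 0.03 in WT and 5.66 ± 0.05 in VEC (difference 0.06, adjusted p = 0.585). Cdh2 differed by -0.002 (adjusted p = 0.993), Vim, already at 12.41 ± 0.03 in VEC, by 0.02 (adjusted p = 0.949), and Fn1 by -0.12 (adjusted p = 0.203). The transcription factor genes Snai1, Snai2, Zeb2 and Twist2 differed by 0.03, 0.06, 0.08 and -0.03 (adjusted p = 0.840, 0.771, 0.391 and 0.820). Zeb1 read 0.21 higher (SE 0.069, adjusted p = 0.0657), Hoxa9 differed by -0.28 (SE 0.101, adjusted p = 0.0911) and Myc by 0.37 (SE 0.150, adjusted p = 0.124). In VEC, Cdh1, Cdh2, Snai2 and Zeb1 read 5.66, 4.25, 4.65 and 5.70, below the array medians of 6.31 to 6.42. Vim and Fn1, at 12.41 and 12.90, lay near the highest value of 13.6. Whether a fall of Cdh1 or a rise of Vim or Fn1 could be seen at such levels was not tested.

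**Figure D1:**
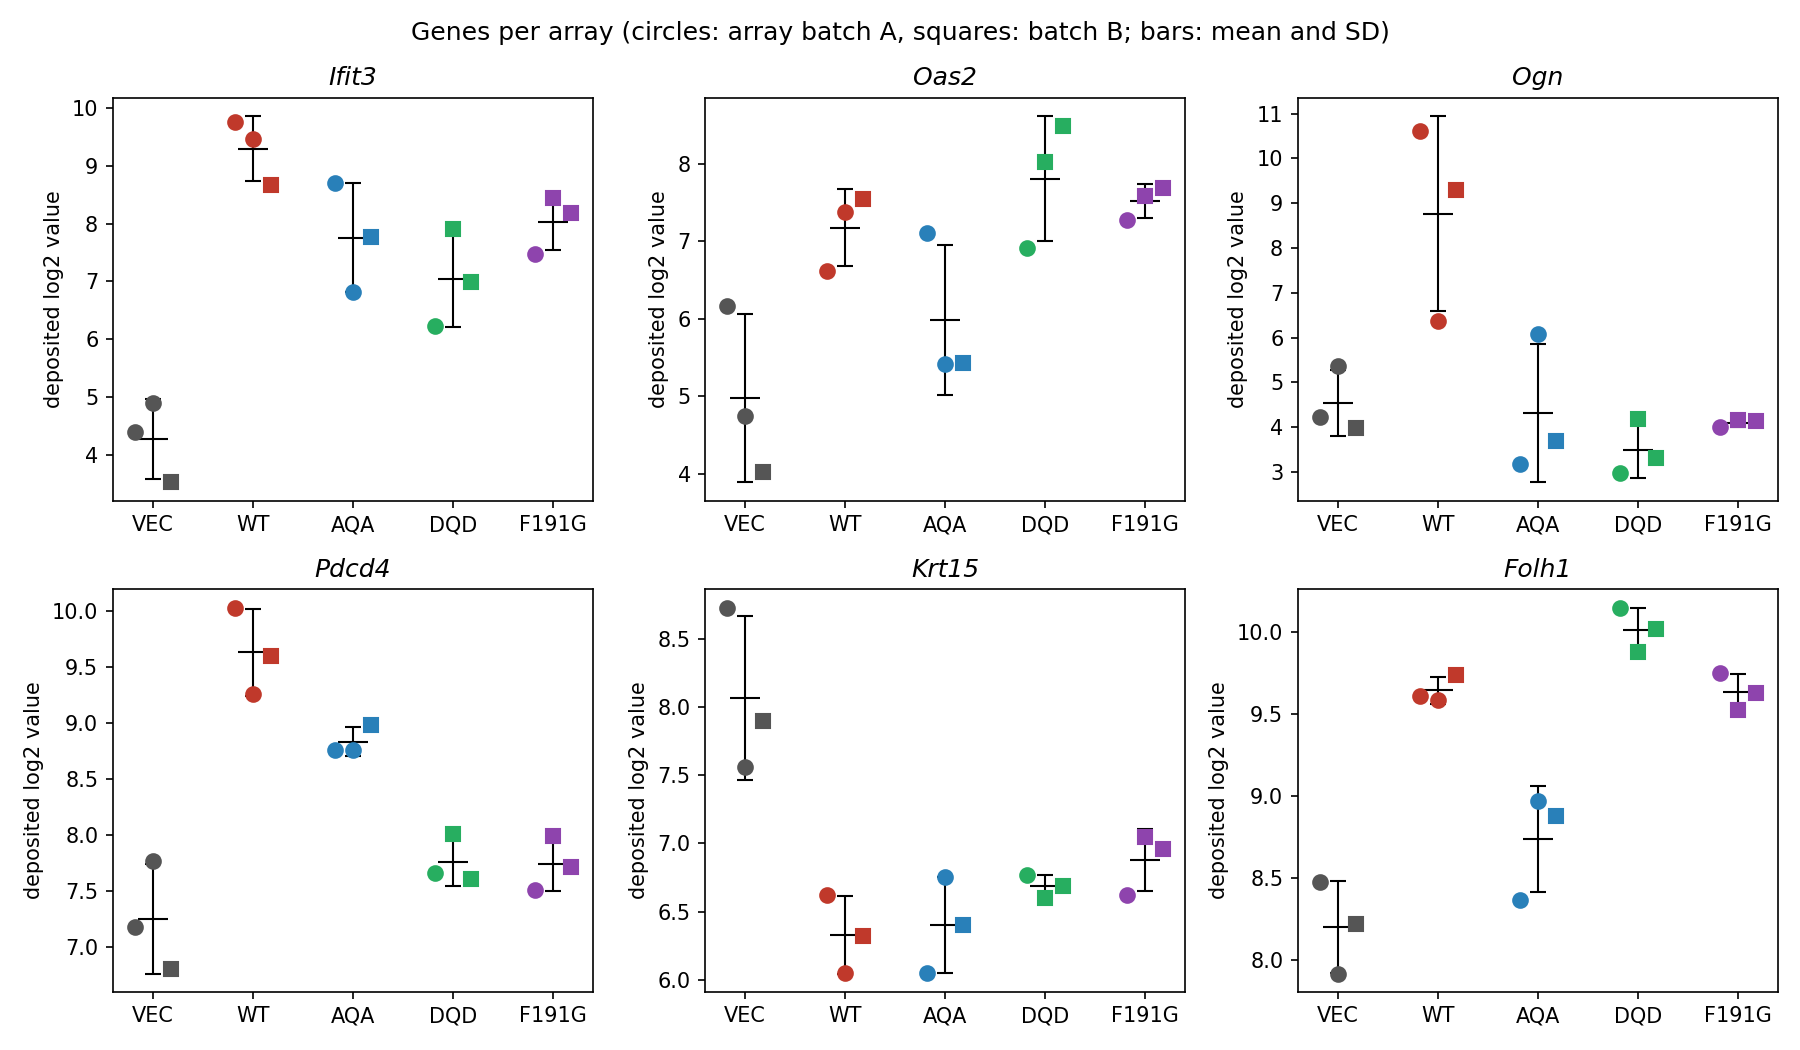
Deposited log2 values of 6 genes on each of the 15 arrays, by group, with mean and SD (n = 3); circles are arrays of batch A and squares of batch B. Ifit3 lies at 3.52 to 4.90 in VEC and at 6.23 or above on every Twist1 array, while Ogn reaches 6.37 to 10.62 in WT.

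F191G against VEC, the other comparison named by the design, asks the same of the Twist box mutant. Ifit3 again showed the largest rise, of 3.77 (SE 0.537, adjusted p = 0.0277), to 8.04 ± 0.50. Folh1, which encodes prostate-specific membrane antigen, rose by 1.43 (SE 0.162, adjusted p = 0.00801), the interferon-inducible gene Ifi27 by 1.39 (SE 0.162) and Rassf4 by 1.07 (SE 0.153), followed by the kinase gene Nuak1 (0.57), Txndc16 (0.54), Ogfr (0.49) and the galactosyltransferase gene B4galt5 (0.48). The cardiac troponin gene Tnnt2 fell by 1.17 (SE 0.187), Cxcl5 by 1.01 (SE 0.127) and Mustn1 by 0.99 (SE 0.152). The neuropeptide gene Npy changed by -1.004 (SE 0.119, adjusted p = 0.00801). Smaller falls were those of Elmod1 (-0.64), the sterol reductase gene Dhcr7 (-0.51), the retinaldehyde dehydrogenase gene Aldh1a3 (-0.51), Coq3 (-0.50), Cpn1 (-0.47) and Olfr513 (-0.37).

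A total of 19 genes was called between F191G and VEC, 9 higher and 10 lower, with 4 and 3 at least 2-fold (2263 genes had an unadjusted p under 0.05). By limma the count was 0 without F191G replicate A (1656 at an unadjusted p under 0.05), without F191G replicate C (2179) or without VEC replicate C (1203), 5 without F191G replicate B and 7 without VEC replicate A. It was 0 within batch A (1094 at an unadjusted p under 0.05), 51 within batch B and 42 without WT replicate A, which widens the spread shared by all groups. Without a batch term it was 86, and with the Twist1 value as a covariate 1. Of the 18 genes named above, 5 were still called without VEC replicate A or F191G replicate B and 10 without VEC replicate B. Median centring, which moved all genes by 0.034, gave 5 higher and 3 lower in place of 9 and 10.

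Of the 41 interferon response genes, 1 rose and 0 fell in F191G against VEC over all genes, and 30 rose and 1 fell adjusted over the list alone. The median was 0.82, with camera adjusted p = 1.08e-31, and adjusted p = 0.336 with an estimated correlation. Oas1b read 1.68 higher (SE 0.309, adjusted p = 0.0750), Irf9 1.13 higher (adjusted p = 0.0947) and Ddx58 1.93 higher (adjusted p = 0.0947). Single called members did not hold: by limma 0 interferon genes were called without VEC replicate A, VEC replicate C or any 1 F191G array (28 to 31 at an unadjusted p under 0.05). Of 36 cholesterol and lipid synthesis genes, Dhcr7 alone fell (4 fell adjusted over the list alone), with camera adjusted p = 5.66e-05, and adjusted p = 0.524 with an estimated correlation. Of 49 cytokine genes, Cxcl5 alone fell (4 adjusted over the list alone), with camera adjusted p = 0.00242, and adjusted p = 0.408 with an estimated correlation; Cxcl2 read -2.15 (SE 0.570, adjusted p = 0.187) and Nfkbia -1.31 (SE 0.375, adjusted p = 0.219). The 26 haematopoietic markers had a median of -0.08 with 0 members called by limma, also adjusted over the list alone (5 at an unadjusted p under 0.05; camera adjusted p = 0.0293, and adjusted p = 0.617 with an estimated correlation). That call ended without F191G replicate A (0.0847) or VEC replicate C (0.252), with quantile normalization (0.184) and without the dimmest genes (0.429). Fry called 0 of the 23 lists (5 at an unadjusted p under 0.05), with adjusted p = 0.0655 for interferon response, 0.117 for cholesterol and lipid synthesis, 0.0573 for cytokines and 0.192 for haematopoietic markers. Without F191G replicate A, F191G replicate C or VEC replicate C limma called 0 cytokine genes (9, 12 and 10 at an unadjusted p under 0.05), and 0 cholesterol genes without those, F191G replicate B or VEC replicate B (4 to 7), against 2 without VEC replicate A. With WT replicate A left out, 3 interferon genes rose and 3 cytokine genes fell. Of the 53 cell cycle genes, 0 rose and 0 fell by limma (2 at an unadjusted p under 0.05), also adjusted over the list alone, with a median of 0.02 and camera adjusted p = 0.196.

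**Figure D2:**
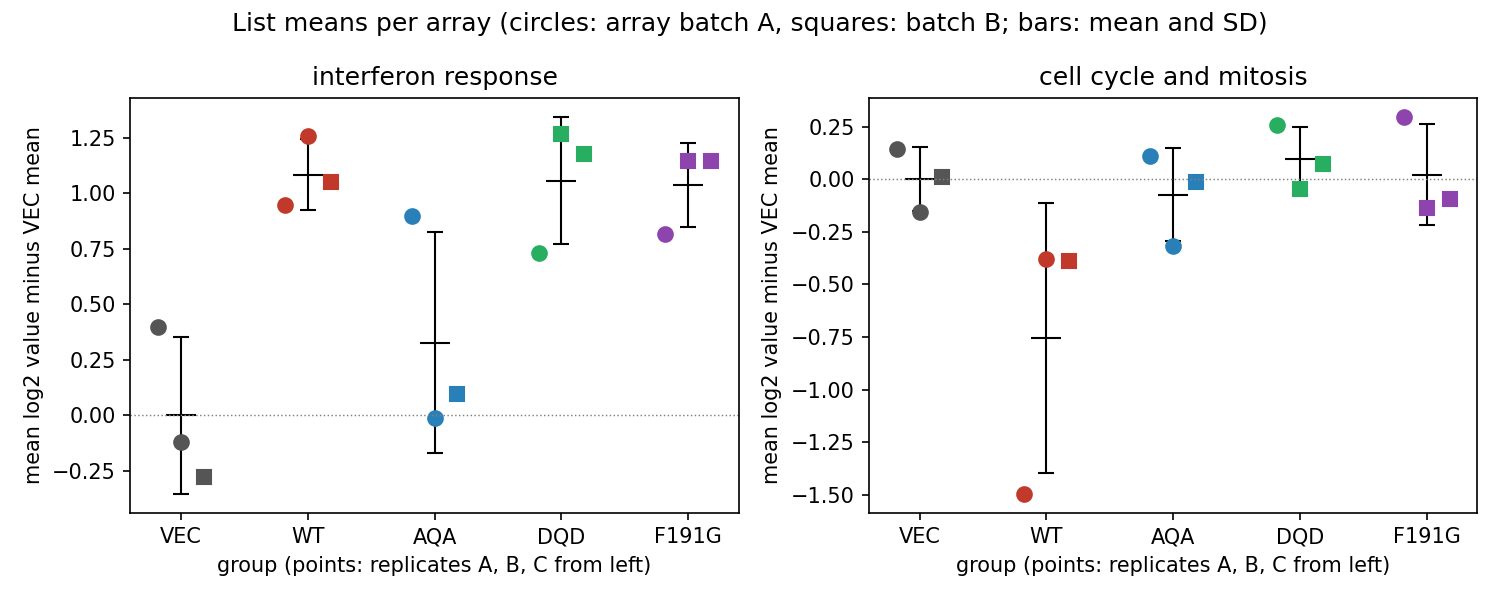
Mean of the interferon response list (41 genes) and of the cell cycle list (53 genes) on each array, relative to the VEC mean, in log2 units, with group mean and SD (n = 3). Interferon means lie at 0.73 or above in WT, DQD and F191G, and the cell cycle mean of WT replicate A is -1.49.

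The direct comparison of F191G with WT sets the mutant beside the wild-type protein. Higher in F191G were the centromere gene Cenpk by 1.39 (SE 0.359, adjusted p = 0.0420), Dscc1 by 1.39 (1.385, SE 0.347), Atad5 by 1.32 (SE 0.350), Ncapg2 by 1.31 (SE 0.359), Fancb by 1.21 (SE 0.332), the polymerase gene Pola1 by 1.19 (SE 0.323), the exonuclease gene Exo1 by 1.15 (SE 0.318), Rad51ap1 by 1.12 (SE 0.264) and the cyclin gene Ccne2 by 1.11 (SE 0.233). Krt6a was higher by 1.14 (SE 0.321, adjusted p = 0.04996). Ogn was lower in F191G (-4.67, SE 0.935, adjusted p = 0.0294), as were Angptl7 (-4.60, SE 0.858) and Igfbp5 (-2.88, SE 0.611). Klhl24 (-2.55, SE 0.352), the histone demethylase gene Kdm7a (-2.16, SE 0.316), Trp53inp1 (-1.94, SE 0.309), the haptoglobin gene Hp (-1.90, SE 0.464), Pdcd4 (-1.90, SE 0.239, adjusted p = 0.0173), Btg2 (-1.85, SE 0.437) and the arginase gene Arg1 (-1.82, SE 0.379) were lower as well. Without WT replicate A, Cenpk (0.92), Atad5 (0.84), Ncapg2 (0.81), Fancb (0.75), Pola1 (0.75), Exo1 (0.71), Ogn (-3.79) and Igfbp5 (-2.25) lost their calls, and Angptl7 differed by -3.85; without F191G replicate A Dscc1 differed by 0.90. With WT replicate B left out, Ogn differed by -5.81, Angptl7 by -5.67 and Igfbp5 by -3.55. Of these 20 genes, 7 were still called without WT replicate A, 0 by limma without F191G replicate A, 6 without F191G replicate B and 4 without F191G replicate C.

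Between F191G and WT 1375 genes were called, 613 higher and 762 lower, with 19 and 76 at least 2-fold. The count was 150 without WT replicate A (148 shared), 0 by limma without F191G replicate A (2791 at an unadjusted p under 0.05), 226 without F191G replicate B, 106 without F191G replicate C and 2952 without WT replicate B. By limma it was 0 within batch A (3641 at an unadjusted p under 0.05), 14 within batch B, and 0 with only the 6 arrays compared (3194). It was 2908 without a batch term and 467 with the Twist1 value as a covariate. Median centring, which moved all genes by 0.062, gave 1143 higher and 490 lower.

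Of 53 cell cycle genes, 5 rose and 0 fell in F191G against WT (50 rose adjusted over the list alone), with camera adjusted p = 4.86e-21, adjusted p = 0.692 with an estimated correlation and 0.0792 by fry. They include Ccne2, Cdc25a (0.64, SE 0.135), Cdk2 (0.57, SE 0.138) and Cdc6 (0.79, SE 0.213; 0.51 and not called without WT replicate A). WT replicate A, with its list mean of -1.49, enters this difference. The count was 2 without WT replicate A, 43 without WT replicate B, 34 without WT replicate C, 1 without F191G replicate B, and 0 by limma without F191G replicate A or C (10 and 49 at an unadjusted p under 0.05). Of 43 Myc targets, 10 rose and 0 fell (31 rose adjusted over the list alone), among them Gnl3 (0.41, SE 0.088), Tfrc (0.54, SE 0.129), Wdr43 (0.40, SE 0.097) and Rrp12 (0.63, SE 0.157; 0.38 without F191G replicate A), with camera adjusted p = 1.13e-16, and adjusted p = 0.692 with an estimated correlation. The count was 26 without WT replicate B, 25 without WT replicate C, and 0 by limma without WT replicate A or any 1 F191G array (13 to 33 at an unadjusted p under 0.05). Of 36 cholesterol and lipid genes, 3 rose and 1 fell (8 and 2 adjusted over the list alone): the carboxylase gene Acaca (0.45, SE 0.087), Sqle (0.61, SE 0.126) and Elovl5 (0.36, SE 0.086) rose, and the lipin gene Lpin1 fell by 1.57 (SE 0.391; -0.99 and not called without F191G replicate A). Camera gave adjusted p = 0.00358, adjusted p = 0.692 with an estimated correlation and 0.0987 with quantile normalization, and fry 0.183. The count that rose was 1 without WT replicate A or F191G replicate C, 5 without WT replicate B, 6 without WT replicate C, and 0 by limma without F191G replicate A or B (9 and 16 at an unadjusted p under 0.05).

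Of 49 cytokine and NF-kB genes, 3 fell and 0 rose in F191G against WT (7 fell adjusted over the list alone), namely Nfkb2 (-0.53, SE 0.132), Tnip1 (-0.64, SE 0.177) and Traf1 (-0.30, SE 0.085), with camera adjusted p = 0.000336, and adjusted p = 0.474 with an estimated correlation. The count was 10 without WT replicate B and 0 by limma without WT replicate A or any 1 F191G array (9 to 17 at an unadjusted p under 0.05). Of 44 stress response genes, 9 fell and 0 rose (13 fell and 1 rose adjusted over the list alone), including Xbp1 (-0.75, SE 0.160), the chaperone gene Dnajb9 (-1.09, SE 0.234), Syvn1 (-0.68, SE 0.162) and Atf6 (-0.50, SE 0.119). Camera gave adjusted p = 0.00358, adjusted p = 0.692 with an estimated correlation and 0.059 without F191G replicate A, and 8 members fell without Ddr2, a collagen receptor gene. The count was 16 without WT replicate B, 2 without F191G replicate B, and 0 by limma without WT replicate A, F191G replicate A or F191G replicate C (13, 13 and 18 at an unadjusted p under 0.05). The interferon list was not called (median 0.03, camera adjusted p = 0.949), with 1 of 41 members falling (0 adjusted over the list alone). None of the transition markers passed the test: Cdh1 differed by -0.18 (adjusted p = 0.0874), Zeb1 by -0.23 (adjusted p = 0.0595), Vim by 0.06 (adjusted p = 0.789), Fn1 by 0.01 (adjusted p = 0.945), Cdh2 by -0.09 (adjusted p = 0.453), Snai1 by -0.08, Snai2 by -0.08, Zeb2 by -0.02, Twist2 by -0.06, Hoxa9 by 0.14 and Myc by 0.12 (adjusted p from 0.414 to 0.886 for these 6).

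The effects of WT and F191G over VEC were set side by side. Of the 19 genes called in F191G, 8 were higher and 9 lower in both comparisons, among them Ifit3, Folh1 and Rassf4 on the higher side and Cxcl5, Tnnt2 and Npy on the lower, against 0.64 and 0.57 for independent lists of these sizes, and 0 went in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 0.0185, against 0.0060 in simulated unchanged groups sharing the VEC arrays, a difference of 0.0126. The observed r was 0.41 and the simulated 0.49. Fold changes varied beyond the modelled noise, by a variance of 0.0683 in WT and 0.0133 in F191G, which the simulation lacks. Such variation, where not shared, lowers r, so an r below the simulated one does not show less agreement. The covariance difference was 0.0013 without VEC replicate C, 0.0257 without F191G replicate A, 0.0073 without F191G replicate B, -0.0162 within batch A and 0.0393 within batch B. The 3 VEC arrays are too few to split, so part of the overlap may come from the shared arrays. The fold changes of WT over VEC and of F191G over WT, which share the WT arrays with opposite sign, called 955 genes in opposite directions, 1 lower in both and 0 higher in both by limma, against 88.85, 43.59 and 43.27 for independent lists. Their covariance was -0.0617 against -0.0060 simulated, and r was -0.83 against -0.49. A gene that differs in WT alone, or on WT replicate A, is pulled opposite ways in these comparisons. Opposite calls are thus built in, and neither independent lists nor unchanged simulated groups are a reference for them. These values do not show that F191G reverses changes made by WT.

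The other forms were compared in the same way. AQA and WT shared 65 genes higher and 42 lower than VEC, Pdcd4 and Krt15 among them, against 6.99 and 4.06 for independent lists (covariance 0.0250, simulated 0.0060; r 0.52, simulated 0.50). DQD and WT shared 38 higher and 15 lower, against 5.65 and 4.41 (covariance 0.0094, simulated 0.0060; r 0.18, simulated 0.49). F191G and DQD, with 6 genes higher and 4 lower in both, had a covariance of 0.0231 (simulated 0.0066) and r of 0.76 (simulated 0.52). F191G and AQA shared 5 higher and 8 lower (covariance 0.0158, simulated 0.0060; r 0.58, simulated 0.49), and AQA and DQD 18 higher and 7 lower (covariance 0.0184, simulated 0.0060; r 0.57, simulated 0.49). Genes called in opposite directions numbered 0 by limma in each of these pairs. The VEC arrays are shared here too, so part of each excess may come from them. Observed and simulated r are again on unlike scales, since the simulation holds noise alone.

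**Figure D3:**
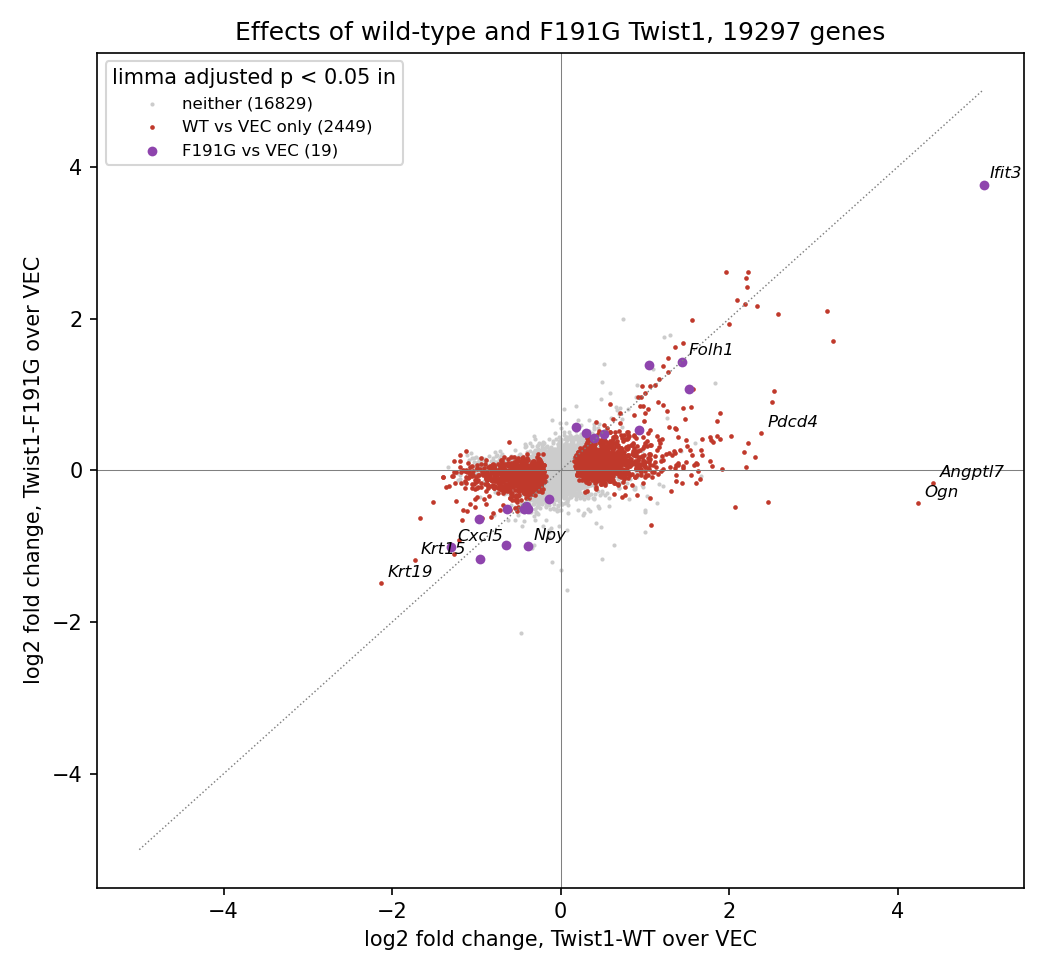
Log2 fold changes over VEC of 19297 genes in WT (horizontal) and F191G (vertical), coloured by the comparison in which limma called them; the dotted line marks equal change. Ifit3 lies far out on both axes (5.02 and 3.77), while Ogn and Angptl7 lie far out only along the WT axis (4.24 and 4.42).

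AQA and DQD are further mutant forms of Twist1, tested against VEC. In AQA, Ifit3 rose by 3.49 (SE 0.525, adjusted p = 0.0176), the selenium-binding protein gene Selenbp1 by 1.61 (SE 0.298), Pdcd4 by 1.58 (SE 0.233) and Pjvk by 1.19 (SE 0.228). Krt15 fell by 1.66 (SE 0.258), Tnnt2 by 1.26 (SE 0.183), the prolyl hydroxylase gene P4ha3 by 1.15 (SE 0.234) and the tight junction gene Cldn1 by 0.97 (SE 0.188). In all 170 genes were called, 99 higher and 71 lower. By limma the count was 0 without VEC replicate C (1913 at an unadjusted p under 0.05) or AQA replicate C (1791), 1 without AQA replicate A, 32 without VEC replicate A, and 0 within batch A (988) and batch B (3329). It was 433 without WT replicate A, 413 without a batch term, 944 with array weights, 26 with only the 6 arrays compared and 3 with the Twist1 value as a covariate. AQA replicate A had a weight of 2.78, against 0.72 and 0.77 for replicates B and C. Of the 8 genes named above, 2 were still called without VEC replicate A and 0 by limma without AQA replicate A, AQA replicate C or VEC replicate C. Median centring gave 92 higher and 42 lower.

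Of the 41 interferon genes, 2 rose in AQA against VEC, Ifit3 and Ifit2 (0.57, SE 0.103), also 2 adjusted over the list alone, with camera adjusted p = 0.000272, and adjusted p = 0.761 with an estimated correlation. The call ended without AQA replicate A (adjusted p = 0.637) or VEC replicate C (0.0624), and fry gave 0.461. The list mean was 0.90 on AQA replicate A and -0.01 and 0.09 on replicates B and C. Of 48 hypoxia and glycolysis genes, the growth factor gene Vegfb rose (0.42, SE 0.079; 15 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.16e-06, and adjusted p = 0.165 with an estimated correlation). Of 44 stress response genes, Cth (0.79, SE 0.105) and the collagen receptor gene Ddr2 (0.41, SE 0.079) rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.93e-05, and adjusted p = 0.294 with an estimated correlation). Without Ddr2 1 rose (camera adjusted p = 8.41e-05). Of 49 cytokine genes Cxcl5 fell by 0.85 (SE 0.124; 1 adjusted over the list alone; camera adjusted p = 0.0451, and adjusted p = 0.607 with an estimated correlation). The 38 integrin and focal adhesion genes had a median of -0.14 with 0 members called by limma (13 at an unadjusted p under 0.05; 4 lower adjusted over the list alone; camera adjusted p = 1.0e-04, and adjusted p = 0.165 with an estimated correlation). The cytokine call ended without VEC replicate A (0.164), AQA replicate A (0.114) or AQA replicate C (0.0699), without a batch term (0.0501) and with quantile normalization (0.0762), and fry did not call the stress response list (0.117). In each of these lists limma called 0 members without AQA replicate A, AQA replicate C or VEC replicate C (3 to 17 at an unadjusted p under 0.05). Without VEC replicate A it called 0 interferon and 0 hypoxia genes (11 and 18 at an unadjusted p under 0.05) and 1 stress response gene. Without AQA replicate B 7 hypoxia genes rose. Without WT replicate A 5 hypoxia genes rose, 3 cytokine genes and 2 integrin genes fell, and 2 mesenchymal genes rose and 2 fell. Camera called 8 lists in all, the others being mesenchymal factors, collagens and matrix proteins, and haematopoietic markers. Their medians were -0.11, -0.09 and -0.09, with camera adjusted p = 0.0329, 0.0329 and 0.0451, and adjusted p = 0.294, 0.761 and 0.761 with an estimated correlation. Ddr2, the 1 called member of the mesenchymal list, rose (2 rose and 3 fell adjusted over the list alone). Of the other 2 lists limma called 0 members, also adjusted over the list alone. The mesenchymal call ended without VEC replicate A (0.0587) or AQA replicate C (0.125), with quantile normalization (0.0762) and without the dimmest genes (0.0607). The collagen call ended without AQA replicate A (0.0672) or AQA replicate C (0.141), and the haematopoietic call without AQA replicate A (0.147), VEC replicate C (0.191) or AQA replicate C (0.141), with quantile normalization (0.192) and without the dimmest genes (0.203). Fry gave 0.117 for both.

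In DQD against VEC the largest rises were interferon-stimulated genes: Ifitm3 by 2.86 (SE 0.554, adjusted p = 0.0474), Oas2 by 2.82 (SE 0.578), Ifit3 by 2.77 (SE 0.537) and Oasl2 by 2.53 (SE 0.486). Krt15 fell by 1.38 (SE 0.264), Npy by 0.73 (SE 0.119), S100a4, which encodes a calcium-binding protein, by 0.62 (SE 0.115) and Tsnax by 0.62 (SE 0.103). Without DQD replicate A Oas2 differed by 3.50 and Ifit3 by 3.38, and without VEC replicate C Ifitm3 by 2.24 and Oas2 by 2.11, none of them called there (adjusted p = 0.0915 and 0.256). Of the 41 interferon genes, 10 rose and 0 fell (29 and 2 adjusted over the list alone), Oas1b (1.73, SE 0.309) and Gbp7 (2.15, SE 0.398) among them, with camera adjusted p = 4.24e-22, and adjusted p = 0.576 with an estimated correlation. Of 36 cholesterol genes, Dhcr7 (-0.39, SE 0.074), Mvd (-0.52, SE 0.105) and Pmvk (-0.30, SE 0.062) fell (5 adjusted over the list alone; camera adjusted p = 0.00514, and adjusted p = 0.576 with an estimated correlation), and of 51 collagens and matrix proteins the laminin gene Lama4 fell by 0.45 (SE 0.085; 13 adjusted over the list alone; camera adjusted p = 8.59e-05, and adjusted p = 0.576 with an estimated correlation). The interferon count was 14 without VEC replicate A, and 0 by limma without any 1 of the other 5 arrays (24 to 34 at an unadjusted p under 0.05). With WT replicate A left out, 21 interferon genes rose and 1 fell, and 2 collagen or matrix genes fell. The cholesterol count was 5 without VEC replicate A and 0 by limma without any 1 of the others (5 to 9), and its camera call ended without VEC replicate B (0.157) or DQD replicate C (0.0623). Lama4 lost its call without any 1 of the 6 arrays, and without VEC replicate A 1 other collagen or matrix gene fell. Camera called 8 lists in all, among them haematopoietic markers and endothelial and fibroblast markers, with medians of -0.14 and -0.16 and 0 members called by limma (10 and 12 at an unadjusted p under 0.05, 5 and 0 adjusted over the list alone). With median centring these medians were -0.074 and -0.091. The haematopoietic call ended without DQD replicate A (0.0562), DQD replicate B (0.0507) or VEC replicate C (0.165) and without the dimmest genes (0.0859). Quantile normalization ended 4 of the 8 calls, those of haematopoietic markers (0.652), endothelial and fibroblast markers (0.41), cytokines (0.0544) and cell cycle genes (0.547), and 5 of the 8 ended without at least 1 array. In all 157 genes were called, 80 higher and 77 lower. The count was 2 without DQD replicate A or C, 1 without DQD replicate B or VEC replicate C, 20 without VEC replicate B, 0 within batch A by limma (1516 at an unadjusted p under 0.05), 46 within batch B and 616 without WT replicate A. It was 1444 without a batch term, 1757 with array weights, 322 over all probe sets, 53 with a variance trend and robust moderation, 12 with only the 6 arrays compared and 1 with the Twist1 value as a covariate. DQD replicate A had a weight of 1.97, against 0.66 and 1.14 for replicates B and C. Quantile normalization left 1 gene called, Folh1 (1.75, adjusted p = 0.00187), and ended the call of each gene named above for DQD against VEC. Median centring, which moved all genes by 0.071, gave 301 higher and 37 lower.

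Against WT, AQA cells had lower Angptl7 (-4.50, SE 0.837, adjusted p = 0.0455), Ogn (-4.45, SE 0.912), Lgals3bp (-2.19, SE 0.429) and the small RNA gene Scarna13 (-1.24, SE 0.260). The glycogen branching enzyme gene Gbe1 was higher by 0.93 (SE 0.184), the circadian repressor gene Ciart by 0.85 (SE 0.175), Fancl by 0.81 (SE 0.145) and Tstd3 by 0.75 (SE 0.137). Of 41 interferon genes, 0 were called by limma over all genes (28 at an unadjusted p under 0.05) and 21 were lower adjusted over the list alone (median -0.69, camera adjusted p = 1.03e-10, and adjusted p = 0.263 with an estimated correlation). Of 53 cell cycle genes, 0 were called by limma over all genes (44 at an unadjusted p under 0.05) and 42 were higher adjusted over the list alone (median 0.71, camera adjusted p = 9.29e-20, and adjusted p = 0.263 with an estimated correlation), WT replicate A at -1.49 being part of the difference. Without WT replicate A the cell cycle median was 0.30, with 16 members at an unadjusted p under 0.05 by limma. Without WT replicate B 5 interferon genes were lower and 30 cell cycle genes higher, and without AQA replicate B 2 and 5. Camera called 13 lists in all, with 2 of 36 cholesterol genes rising (17 adjusted over the list alone; camera adjusted p = 1.18e-09, and adjusted p = 0.263 with an estimated correlation), Sqle (0.64, SE 0.123) and Elovl5 (0.45, SE 0.084). The cholesterol count was 9 without WT replicate B, 8 without AQA replicate B and 0 by limma without any 1 of the other 4 arrays (13 to 19 at an unadjusted p under 0.05). Of the 13 calls, 6 ended without at least 1 array and 2 with quantile normalization, and fry did not call the cell cycle and Myc target lists (0.0707 for each). In all 140 genes were called, 59 higher and 81 lower. By limma the count was 0 without WT replicate A (2855 at an unadjusted p under 0.05), WT replicate C (4688), AQA replicate A (2976) or AQA replicate C (3012), 2411 without WT replicate B and 1270 without AQA replicate B. It was 0 within batch A (1668), 74 within batch B, 0 with only the 6 arrays compared (3227) and 0 with the Twist1 value as a covariate (4656). Without a batch term it was 1501, with array weights 2843, over all probe sets 228 and without the dimmest genes 832. WT replicate B had a weight of 3.36, against 0.24 and 0.94 for WT replicates A and C, and AQA replicate A had 2.78. Quantile normalization gave 230 higher and 284 lower, and median centring 42 higher and 19 lower. Without WT replicate A, Angptl7 (-3.67) and Ogn (-3.48) lost their calls, and of the 8 genes named above limma called 0. Angptl7 and Ogn differed by -5.69 and -5.71 without WT replicate B and by -5.37 and -5.38 without AQA replicate B, and Ogn by -3.85, not called, without AQA replicate A.

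DQD against WT gave the most calls of the 8 comparisons, 4735 genes, 2272 higher and 2463 lower. Ogn (-5.27, SE 0.935, adjusted p = 0.0094), Angptl7 (-5.23, SE 0.858), Igfbp5 (-3.55, SE 0.611) and the cytochrome gene Cyp2b10 (-2.68, SE 0.661) were lower, and Cck (1.70, SE 0.479), Cenpk (1.60, SE 0.359), Ppbp (1.59, SE 0.370) and Fbxo5 (1.59, SE 0.462) higher. Without WT replicate A Ogn differed by -4.39, Angptl7 by -4.48, Igfbp5 by -2.92, Cyp2b10 by -1.91, Cck by 1.03 and Fbxo5 by 0.93, and all 8 kept their calls. The first 4 differed by -6.41, -6.31, -4.22 and -3.37 without WT replicate B, and Cck by 2.40 without WT replicate C; without DQD replicate A limma called 0 of the 8. Of 53 cell cycle genes, 42 rose and 1 fell (51 and 1 adjusted over the list alone), with Cdk2 up 0.71 (SE 0.138), camera adjusted p = 6.73e-19, and adjusted p = 0.572 with an estimated correlation. The count was 25 without WT replicate A, 26 without DQD replicate B, 15 without DQD replicate C and 0 by limma without DQD replicate A (34 at an unadjusted p under 0.05). Of 43 Myc targets, 28 rose and 0 fell (34 adjusted over the list alone), with Npm1 up 0.32 (SE 0.073), camera adjusted p = 3.96e-14, and adjusted p = 0.572 with an estimated correlation. The count was 14 without WT replicate A and 0 by limma without DQD replicate A (25 at an unadjusted p under 0.05). Of 44 stress response genes, 21 fell and 2 rose (22 and 5 adjusted over the list alone), with the transcription factor gene Atf3 down by 1.36 (-1.362, SE 0.262), camera adjusted p = 0.0358, and adjusted p = 0.572 with an estimated correlation. Without Ddr2 that call ended (camera adjusted p = 0.059), with 20 falling and 2 rising. Of 49 epithelial junction and keratin genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone), including the protease gene Prss8 (-2.01, SE 0.395), plakoglobin gene Jup (-1.11, SE 0.249) and Cdh1 (-0.27, SE 0.064), with camera adjusted p = 0.0300, and adjusted p = 0.572 with an estimated correlation. The median of the epithelial list was -0.143, and -0.044 with median centring. Cdh1 read 5.72 in WT, below the array medians. In this list 4 fell without WT replicate A and 5 without WT replicate C, and without DQD replicate A limma called 0 members of it or of the stress response list (13 and 23 at an unadjusted p under 0.05). The epithelial call ended without DQD replicate A (0.0645) or WT replicate C (0.0545), and the stress response call without DQD replicate A (0.0645) or DQD replicate C (0.0811). Camera called 11 lists in all. Quantile normalization ended 6 of these calls, that of the epithelial list among them (0.0615), and 4 of the 11 ended without at least 1 array. The count of called genes was 2118 without WT replicate A (2095 shared), 0 by limma without DQD replicate A (5504 at an unadjusted p under 0.05) and 3122 without DQD replicate B, 0 within batch A (4287), 330 within batch B and 0 with only the 6 arrays compared (5251). Median centring, which moved all genes by 0.098, gave 3677 higher and 999 lower.

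DQD and AQA, compared directly, differed in 5 called genes, a count that was 156 without a batch term and 1670 with array weights. Those weights were 2.78, 0.72 and 0.77 for AQA replicates A, B and C and 1.97, 0.66 and 1.14 for DQD. The weighted count thus rests largely on replicate A of each form. Folh1 was 1.27 higher in DQD (SE 0.162, adjusted p = 0.0179), Atp6v1b2, a subunit of the vacuolar proton pump, 0.63 higher (SE 0.077), Gtf2h1, a subunit of a general transcription factor, 0.55 higher (SE 0.080) and Dlg5 0.43 higher (SE 0.062), and the decapping enzyme gene Dcps was lower (-0.56, SE 0.063, adjusted p = 0.0131). Of 41 interferon genes, 0 were called by limma over all genes (27 at an unadjusted p under 0.05) and 25 were higher and 1 lower in DQD adjusted over the list alone (median 0.72, camera adjusted p = 4.3e-15, and adjusted p = 0.525 with an estimated correlation). Camera called 8 lists in all, of which 4 ended without at least 1 array and 2 with quantile normalization. Fry called 0 lists (4 at an unadjusted p under 0.05), with adjusted p = 0.237 for the interferon list. By limma 2811 genes had an unadjusted p under 0.05. The count of 5 was 0 without AQA replicate A, AQA replicate C, DQD replicate A or DQD replicate C (2111, 2475, 1994 and 2791 at an unadjusted p under 0.05) and 2 without DQD replicate B, 0 within batch A (1229), 29 within batch B and 162 without WT replicate A. It was 21 with only the 6 arrays compared, 16 without the dimmest genes and 3 over all probe sets. Median centring gave 24 higher and 4 lower, and quantile normalization left Folh1 (1.23) and Dcps (-0.62) called.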

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

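Leaving WT replicate A out of comparisons it is not part of and leaving Ddr2 out of the stress response list were chosen after the data were seen; all other alternatives were fixed earlier. Over the alternatives, 51 of the recomputed gene counts stayed within 1.5 times and 105 moved further. Of the single gene results 5027 kept their side of the threshold, 1429 lost and 361 gained a call (limma, adjusted p). Of those called in the full model or in the alternative, 0 reversed direction. Direction was not compared for results called in neither. Of the list results 587 kept and 174 lost their call and 0 reversed; with an estimated correlation every list call was lost. In the order of comparisons given with the gene counts, camera called 6, 4, 5, 8, 8, 13, 11 and 8 lists, of which quantile normalization kept 6, 3, 4, 5, 4, 11, 5 and 6. Fry, which does not compare a list with other genes, called 7, 0, 6, 4, 13, 13, 17 and 0 lists (8, 5, 10, 8, 15, 15, 17 and 4 at an unadjusted p under 0.05), among them 5, 0, 3, 4, 7, 11, 10 and 0 of those called by camera. Of 193 called results of named genes, 193 held without a batch term, 182 with array weights, 178 over all probe sets, 167 with median centring, 161 with quantile normalization, 157 with a variance trend and robust moderation, 73 with the Twist1 covariate, 62 within batch B, 13 with only the groups compared and 0 within batch A, and 177 of 177 without the dimmest genes. The limma adjusted p of the Twist1 difference between WT and VEC stayed above 0.05 in every alternative. It came closest, at 0.0507, without VEC replicate B. Unless stated, the cause of a move was not tested. Fits within a batch, or of few arrays, have fewer residual degrees of freedom, and a group with 1 array there is assumed to vary like the others. The Twist1 covariate has no value for Twist1 itself, and the comparison of WT and F191G effects none with only 2 groups. That covariate also overlaps with the groups, since Twist1 is the introduced gene. The modelled noise shared by the WT and F191G effects over VEC was 0.0118 with it, against 0.0060 in the full model. Signal over background is not given for these arrays, so what dim genes limit was tested only by leaving out the dimmest 33.3%.

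Counts are in the order WT against VEC, F191G against VEC, F191G against WT, AQA against VEC, DQD against VEC, AQA against WT, DQD against WT and DQD against AQA, with values for the full model of 2466, 19, 1375, 170, 157, 140, 4735 and 5. Without a batch term they were 3188, 86, 2908, 413, 1444, 1501, 6231 and 156. With Twist1 as a covariate they were 17, 1, 467, 3, 1, 0, 4200 and 4. With only the arrays of the groups compared they were 10, 13, 0, 26, 12, 0, 0 and 21. Quantile normalization gave 2644, 16, 1263, 186, 1, 514, 3216 and 2, and median centring 2271, 8, 1633, 134, 338, 61, 4676 and 28. Leaving out the dimmest genes, which lowers the number tested, gave 832 for AQA against WT and 16 for DQD against AQA, and the other 6 counts stayed within 1.5 times. All probe sets gave 2714, 15, 1241, 210, 322, 228, 5666 and 3, a variance trend with robust moderation 2329, 21, 1193, 155, 53, 140, 4648 and 7, and array weights 2311, 24, 1050, 944, 1757, 2843, 6250 and 1670. The weights ran from 0.24 for WT replicate A to 3.36 for WT replicate B, with 2.78 for AQA replicate A. Weighted counts thus rest largely on few arrays. Within batch A limma called 0 in all 8, and within batch B 293, 51, 14, 0, 46, 74, 330 and 29. Without 1 array of the groups compared, counts ran from 128 to 3261, 0 to 21, 0 to 2952, 0 to 219, 1 to 219, 0 to 2411, 0 to 5353 and 0 to 4. Without WT replicate A, comparisons that lack WT gave 42 for F191G against VEC, 433 for AQA against VEC, 616 for DQD against VEC and 162 for DQD against AQA. The 32 counts of 0 by limma, those with the replicate letter included, had 988 to 5504 genes at an unadjusted p under 0.05. The covariance excess of WT and F191G effects, 0.0126 in the full model, was 0.0045 with the Twist1 covariate, 0.0393 within batch B, -0.0162 within batch A, where it reversed, and 0.0013 to 0.0257 without 1 array.

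The replicate letter as a block in place of the batch term gave 1961, 7, 927, 44, 2, 0, 4376 and 3 genes. Of the 193 named results 138 held. With the block and the batch term together 100 held, and the counts were 1523, 0, 251, 25, 1, 0, 2646 and 0, and the covariance excess was 0.0053; of the list calls 0, 1, 0, 2, 0, 0, 1 and 1 ended. No pairing of the arrays by letter was seen: of 30 same-letter pairs across groups, 6 had deviations that correlated above 0.1, the median was -0.057 (other letters 0.016), and 0 of the 15 arrays lay closest to their own letter. The outlying WT A weighs on this, at -0.501 with AQA A, -0.576 with DQD A, -0.702 with F191G A and -0.058 with VEC A. Sets of arrays handled together are therefore not excluded.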

Other observations

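Tests in this part were chosen after the results were seen, except the counts over other splits and the test of a regression on Twist1.

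Across the 4 Twist1 forms, 6 genes were called against VEC in the same direction in every form, 3 higher and 3 lower; these comparisons share the VEC arrays. The count was 0 by limma without VEC C, AQA A, AQA C, DQD B, F191G A or F191G C, where at least 1 form had at most 1 gene called, and 1 to 15 without any 1 of the other arrays. With quantile normalization DQD called only Folh1, so none of the 6 was called in every form. Ifit3 rose by 5.02 in WT, 3.49 in AQA, 2.77 in DQD and 3.77 in F191G, Ifi27 by 1.05 to 1.39 (1.047, 1.145, 1.278 and 1.391), and Txndc16 by 0.93, 0.71, 0.38 and 0.54. Aldh1a3, which makes retinoic acid, fell by 0.44, 0.58, 0.50 and 0.51 in that order and Cpn1 by 0.41, 0.45, 0.35 and 0.47. Npy changed by -0.39, -0.80, -0.73 and -1.004. Folh1, chosen for description after its values were seen, read 8.21 ± 0.28 in VEC, 8.74 ± 0.32 in AQA, 9.65 ± 0.08 in WT, 9.64 ± 0.11 in F191G and 10.01 ± 0.13 in DQD. It was called higher than VEC in WT (1.44, adjusted p = 0.000929), F191G (adjusted p = 0.00801) and DQD (1.81, adjusted p = 0.000989), not in AQA (0.54, adjusted p = 0.129), and it was lower in AQA than in WT (-0.91, adjusted p = 0.0455). The call between AQA and WT ended without WT replicate A, WT replicate C, AQA replicate A or AQA replicate C, where limma called 0 genes. The F191G call ended likewise without F191G replicate A, F191G replicate C or VEC replicate C.

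WT replicate A lay farther from VEC than the other 2 WT arrays: the SD of its differences across genes was 0.45 against 0.22, and 346 genes lay at least 1 log2 unit from the mean of WT B and C, 109 higher and 237 lower. Random noise on that array is argued against, since across genes (not independent replicates) its difference from WT B and C correlated with their difference from VEC (r = 0.45), and endothelial, fibroblast or neural cells in the culture are argued against, since no measured marker of these types lay more than 0.35 above WT B and C (Col1a2 0.06, Col3a1 0.11). A growth state that varies between cultures is a candidate explanation: over the 12 arrays of the other groups, deviations from group means of the 100 genes that rose most in WT A opposed those of the cell cycle list (r = -0.84, rho = -0.84, permutation p = 0.0014 and 0.0013, 1 relation computed, so adjusted values are equal). The correlation was -0.76 without the 2 farthest arrays, -0.86 within batch A and -0.93 within batch B, though deviations from means of 3 arrays are not fully independent. Blood cells were not excluded, since 1 of the 26 haematopoietic markers, Cd52, read 8.35 against 6.03 (2.33 higher), Cd68 was 0.53 higher and the list mean was the highest of the 15 arrays (0.165, against -0.026 and 0.012 on WT B and C), though Ptprc, which white blood cells share, differed by 0.03; a stronger effect of wild-type Twist1 in that culture stays open as well, as untested.

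Interferon genes were raised on 1 of the 3 AQA arrays: the list mean was 0.90 on AQA A, -0.01 on AQA B and 0.09 on AQA C, while Ifit3 read 8.70, 6.81 and 7.77 there, above the VEC arrays in each. An AQA A array that belongs to another group is argued against, since outside the interferon list it correlated with the other AQA arrays at 0.44 and with no other group above 0.19, a margin of 0.26. Variation between arrays regardless of the introduced gene stays open: the list mean spanned 0.91 over the AQA arrays and 0.68 over the VEC arrays, and 3 arrays per group are too few to set these ranges apart. Whether the AQA form raises the genes stays open too.

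Over all 12 Twist1 arrays the interferon list mean was 0.88 above VEC (exact two-sided permutation p = 0.011 over 455 splits), and 10 of the 12 lay above the highest VEC array, the others being AQA B and AQA C. The difference was 0.63 in batch A and 1.26 in batch B (exact permutation p = 0.01 within batches, 196 splits). Both tests exchange single arrays, as though arrays of the same form were independent, which the labels do not show. VEC is the only group without Twist1, so groups could not be tested as units. The list mean over VEC was 1.08 in WT, 0.33 in AQA, 1.06 in DQD and 1.04 in F191G.

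The Twist1 probe set was at most 0.36 higher in any form than in VEC. Division of each array by its Twist1 value would leave a constant probe set, and it spanned 0.85 over the 15 arrays; residuals of a regression on Twist1 would correlate with it at 0, and the median absolute correlation of the other genes was 0.22. Both forms of normalization are thus argued against for the values used here. A probe set outside the introduced sequence may account for the small difference of 0.36, and this could not be decided without probe positions, so weak introduction of the gene stays open as well.

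The 6 arrays of each comparison make 10 splits, too few for a share under 0.05. In each of the 8 comparisons 1 split, the real one, called the most genes: 2466 for WT against VEC, 19 for F191G against VEC, 1375 for F191G against WT, 170 for AQA against VEC, 157 for DQD against VEC, 140 for AQA against WT, 4735 for DQD against WT and 5 for DQD against AQA. The highest of the other splits was 0 by limma throughout, with 108 to 4207 genes at an unadjusted p under 0.05. Each other split mixes the 2 groups, so a difference between the groups widens the spread there and lowers the count. Their counts of 0 are therefore no reference for chance. For AQA against WT, the split of WT A, AQA B and WT C had the 4207, against 4822 in the real split.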
